A study of Homo sapiens with 6 samples.

How the data were processed

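RNA from THP-1 cells was measured on 6 one-colour Agilent arrays, 3 control and 3 treated, with 62976 spots each, of which 58717 were not control spots. The deposited scanner files hold processed signal intensity in arbitrary units on a linear scale, after background subtraction and spatial detrending by Feature Extraction 11.5.1.1, per the file headers. The deposited value table holds the same intensity for each probe, as the mean over its spots: 98.2% to 98.6% of probes lay within 0.1% of that mean. Its column medians were 1.51, 1.67, 1.43, 1.85, 1.46 and 1.60. No scaling between arrays by the authors was found in either. No reads were aligned, and positions are those of the array annotation on hg19. The displaced columns of treated array 1 were kept except where stated.

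The array holds 50599 distinct probes, 902 of them on 10 spots. Spots of a probe were averaged. Probes were grouped into genes, placed in lists and named by the array's own gene name. Beside it, a current symbol was found by the transcript accession for 28174 probes and by symbol alone for 2618, and 19807 probes matched neither. Signal was put on the log2 scale and the 75th percentile of each array was subtracted. A probe was kept when its spots were well above background, by the scanner software, on at least 3 of 6 arrays, which kept 12250 probes under 10656 names, called genes here. Of these, 7428 are gene symbols, and the rest are accessions, locus or transcript names or, for 530, probe names. A further 128 probes were lost to missing values, and the brightest probe stood for each gene. Depth on an array is its signal over background, and the number of arrays and the spread between them limit the precision. The median residual SD (log2) was 0.967 over all 6 arrays under the scanner-file labels and 0.408 without the 2 dim arrays under the value-table labels.

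Treated and control were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p of 0.05). Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Of 34 lists, 29 had at least 5 measured genes and were tested. The design, lists and naming rule were fixed before the data were examined. Named genes were the 12 with the largest increase and the 12 with the largest decrease among those past the threshold, with no overlap between groups, with the higher group well above background and with a gene symbol. To these were added the receptor and ligand genes CSF1R, CSF2RA, CSF2RB, CSF1 and CSF2. From each described list, up to 4 members with the smallest adjusted p and up to 2 opposite to its majority were added. Under the scanner-file labels only 2 members with the smallest adjusted p were taken, which departs from the fixed rule. Array quality was compared with exact permutation tests. Tables were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

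The comparison was run under the labels of the scanner files, under those of the value table, and with slide as a block where a slide held both groups. Alternatives were other scalings: quantile, median, a normexp background model with an offset of 50, and a percentile over detected spots. Other filters (none, all arrays), the mean of probes, and trend and robust variance were also tried. The displaced columns of treated array 1, and each array in turn, were left out as well. The comparison without the 2 dim arrays was added after the data were seen. Both fits were tested on simulated data, with variances drawn from the limma prior, 5 simulations and 200 changed genes each. At a log2 change of 4, the comparison of 3 against 3 recovered 0.303% of changed genes, and that of the 4 brighter arrays recovered 98.2%. At a log2 change of 2, the latter recovered 11.0%, and with no change both called 0 genes. Each simulated array varied independently with the same spread per gene, so an array that differs as a whole was not simulated.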

Results

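THP-1 is a human monocytic leukaemia line used as a model of monocytes. GM-CSF and M-CSF are growth factors that drive the survival, division and differentiation of myeloid cells. RNA from 3 control samples and 3 samples given 30 ng/ml GM-CSF with 83 ng/ml M-CSF for 24 h was measured on 6 Agilent arrays, each with 62976 spots. The comparison asks which genes both factors together change. The 75th percentile of processed signal was 9.45, 6.08 and 5.95 on control arrays 1 to 3 and 2.40, 8.19 and 2.97 on treated arrays 1 to 3. The share of spots well above background was 31.4%, 25.8% and 25.3% on the control arrays and 8.55%, 29.9% and 12.7% on the treated arrays. The number of arrays and the spread between them limit the precision. The labels do not say whether the samples came from separate cultures, so p-values measure only the spread between samples.

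The deposit holds 2 sets of labels that differ. The column that the value table names control 2 carries the signal of the scanner file named treated 2, with a correlation across probes of 0.9998 against 0.912 for the file of its own name. The column named treated 2 carries the signal of the scanner file named control 2. Results are therefore given under both sets of labels, and arrays are named here by their scanner files. Treated arrays 1 and 3, the 2 dim arrays, are treated under both. On treated array 1 the scanner's grid was displaced by 2 rows over 24.4% of the spots that are not controls, so those values belong to other probes in every fit that holds this array with these columns. Its spots of the same probe had a coefficient of variation of 72.0%, against 8.10% to 10.1% on the other arrays.

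**Figure D1:**
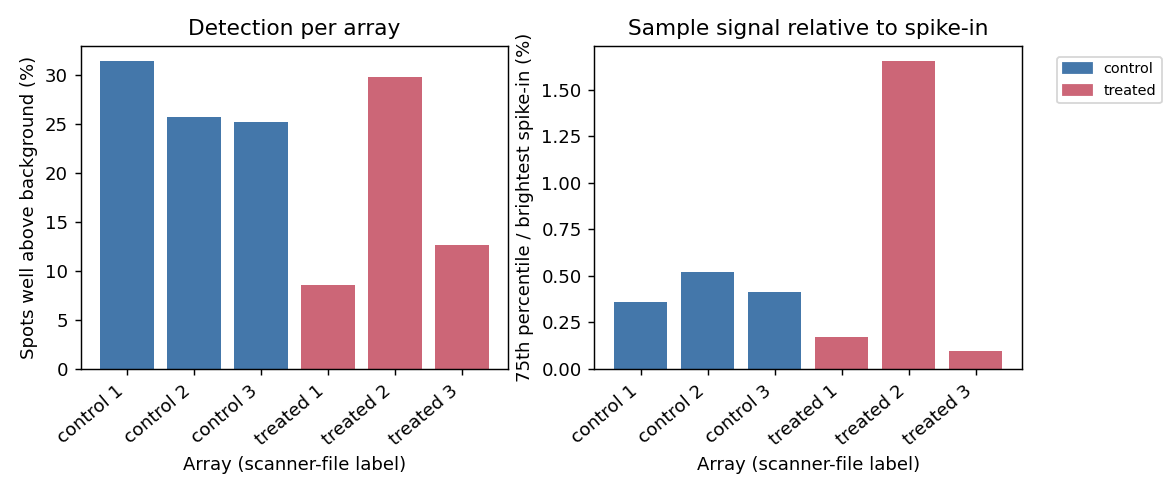
Share of spots well above background (%) and 75th percentile of signal relative to the brightest spike-in (%) on each of the 6 arrays, named by scanner file. Treated array 1 (8.55%) and treated array 3 (12.7%) had the lowest shares of spots, and treated array 2 (29.9%) lay among the controls.

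Under the scanner-file labels, genes of protein synthesis, energy supply and stress defence had lower medians in treated than in control samples as lists, and no gene passed the test alone. The reference genes ACTB, GAPDH, B2M and EEF1A1 were lower too (log2 fold changes -3.07, -2.87, -3.32 and -2.54). Such falls are thus not particular to these lists. On the dim arrays the 75th percentile used for scaling (2.40 and 2.97) lay below the weakest signal called well above background (9.11 and 7.36). It lay above that limit on control array 1 (9.45 against 6.10) and treated array 2 (8.19 against 5.69). On control arrays 2 and 3 it lay slightly below the limit, at 6.08 against 6.20 and 5.95 against 6.52. Scaling of the dim arrays thus rested on undetected signal, and that of control arrays 2 and 3 on signal near the limit. All 35 measured ribosomal protein genes were lower (median log2 fold change -3.13, camera adjusted p = 9.6e-07, adjusted p = 0.697 with an estimated correlation). RPL27, a protein of the large ribosomal subunit (hg19 chromosome 17, 41154694 to 41154753), had a log2 fold change of -5.22 ± 1.96 (SE, 3 samples per group, limma adjusted p = 0.336), and RPS25 of the small subunit had -4.98 ± 1.99. Of 26 genes of oxidative phosphorylation, the mitochondrial route to ATP, 24 were lower (median -2.27, adjusted p = 0.00167, adjusted p = 0.697 with an estimated correlation), with COX7B at -3.30 ± 1.31 and NDUFV1 at -3.40 ± 1.37. Of the genes named from these 10 lists, RPS25 alone was well above background on a dim array (treated array 3), so these fitted values depend on the signal given to undetected spots and are not exact folds. RPL27 had signals of 3349, 1886 and 1665 on the control arrays and 3029 on treated array 2, but was not well above background on the 2 dim arrays. Without these 2 arrays, under the same labels, treated array 2 alone is set against the 3 control arrays. The median was then 0.60 for ribosomal protein genes and 0.58 for oxidative phosphorylation.

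All 14 measured NRF2 oxidative stress genes were lower (median -1.90, adjusted p = 0.00431, adjusted p = 0.697 with an estimated correlation), including the cystine carrier SLC7A11 at -3.01 ± 1.04 and PGD of the pentose phosphate pathway at -3.19 ± 1.30. Of 14 heat shock genes, 13 were lower (median -2.48, adjusted p = 0.00491, adjusted p = 0.697 with an estimated correlation), with the chaperones HSPA1B at -2.28 ± 0.68 and HSPH1 at -3.45 ± 1.33. Of 23 genes of the lysosome, the digestive compartment, 20 were lower (median -1.40, adjusted p = 0.0349, adjusted p = 0.697 with an estimated correlation), with GUSB at -2.99 ± 1.13 and LAMP1 at -3.40 ± 1.38. Of 18 genes of the unfolded protein and integrated stress response, 16 were lower (median -1.50, adjusted p = 0.0368, adjusted p = 0.697 with an estimated correlation), with SLC7A11 again and its partner SLC3A2 at -2.36 ± 0.77. Ribosome biogenesis had 16 of 18 genes lower (median -2.18, adjusted p = 0.0380, adjusted p = 0.697 with an estimated correlation), with the nucleolar proteins NCL at -4.28 ± 1.60 and GNL3 at -3.28 ± 1.29. Glycolysis and hypoxia had 17 of 20 lower (median -1.71, adjusted p = 0.0380, adjusted p = 0.697 with an estimated correlation), with the phosphofructokinase PFKP at -3.42 ± 1.19 and the pyruvate kinase gene PKM2 at -3.05 ± 1.15. Antigen presentation by MHC class I had 12 of 15 lower (median -2.93, adjusted p = 0.0425, adjusted p = 0.697 with an estimated correlation), with TAPBP at -3.94 ± 1.41 and PSMB10 at -3.63 ± 1.51. Mitosis had 20 of 23 lower (median -1.63, adjusted p = 0.0425, adjusted p = 0.697 with an estimated correlation), with CENPF at -2.31 ± 1.09 and PRC1 at -2.42 ± 1.17. Leaving out the 2 dim arrays leaves treated array 2 alone as treated. The medians were then -0.13 for NRF2, 0.25 for heat shock, -0.18 for the lysosome and -0.27 for the unfolded protein response. They were 0.35 for ribosome biogenesis, 0.38 for glycolysis, 0.28 for MHC class I and 0.39 for mitosis.

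The M-CSF receptor gene CSF1R (hg19 chromosome 5, 149432861 to 149432920) had a log2 fold change of -2.18 ± 1.47 (limma adjusted p = 0.396). Its signal was 636 on control array 2, between 13.3 and 22.5 on control arrays 1 and 3 and treated array 2, and not well above background on the 2 dim arrays. CSF2RB, the beta chain of the GM-CSF receptor, was measured on all 6 arrays and had a log2 fold change of 0.52 ± 0.71 (adjusted p = 0.662). The gene of the alpha chain, CSF2RA, was well above background on treated array 2 alone. CSF1, which encodes M-CSF, was well above background on 2 arrays and CSF2, which encodes GM-CSF, on 0.

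By limma, 0 of 10656 genes passed an adjusted p of 0.05, with 1377 at an unadjusted p under 0.05. An ordinary test of each gene, without limma's pooled variance, also gave 0, with 728 unadjusted. The median log2 fold change over all genes was -0.47. In each of the 10 lists, 0 members passed with p adjusted over the list alone. Without treated array 2, 5846 genes passed (1956 higher, 3890 lower), and RPL27, not well above background on the 2 remaining treated arrays, was at least 99.9-fold lower (adjusted p = 8.39e-04). Reference genes were dim on these arrays too: ACTB had signals of 111 and 28.1 there and 3063 to 5925 on the other 4 arrays, EEF1A1 171 and 31.4 against 2116 to 5588, and GAPDH and B2M were not well above background. The scan and the slide coincided and each slide held 1 group under these labels, so slide and treatment cannot be told apart.

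Under the value-table labels, PLAC8, a small myeloid protein, was well above background on the 3 control arrays and on 0 of the 3 treated arrays, at least 19.3-fold lower (fitted log2 fold change -6.57 ± 0.70, SE, limma adjusted p = 0.0780). The calgranulin S100A8 was at least 12.3-fold and the nucleotide receptor P2RY2 at least 8.89-fold lower in the same way, each with the same adjusted p. For such genes the fitted value depends on the signal given to undetected spots. A bound of this kind replaces a treated signal below the detection limit by the weakest signal called well above background on that array. The treated group holds the 2 dim arrays, where reference genes were low too, so the size of these bounds is not particular to these genes. IL1B, an inflammatory cytokine, had 5.52 ± 1.12 (adjusted p = 0.161), and CSF1R had 1.52 ± 1.56 (adjusted p = 0.513). DNA replication genes were lower as a list (camera adjusted p = 5.93e-10, adjusted p = 0.400 with an estimated correlation), and 20 of 23 members fell with p adjusted over the list alone. Ribosomal protein (2.44e-07), mitosis (1.73e-06), myeloid progenitor and azurophil granule (2.88e-06) and oxidative phosphorylation genes (1.26e-05) were also lower as lists by camera adjusted p. Metallothioneins (0.00269), ribosome biogenesis (0.00269), heat shock (0.00632) and glycolysis genes (0.0271) were lower too, and inflammatory cytokines and chemokines were higher (0.0271). With an estimated correlation, none of the 10 lists passed (adjusted p from 0.400 to 0.656).

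Limma gave 0 genes under the value-table labels, with 2189 at an unadjusted p under 0.05. Each slide held both groups under these labels, and with slide as a block PLAC8 was the 1 gene that passed (fitted -6.95 ± 0.68, adjusted p = 0.0407). On slide 1, with 2 control arrays and 1 treated array, 632 genes passed (216 higher, 416 lower). On slide 2, with 1 control array and 2 treated arrays, 2962 passed (622 higher, 2340 lower). On each slide the lone array of a group is assumed to vary like the pair of the other group, which alone gives the spread. IL1B had 8.39 ± 0.46 on slide 1, 3.96 ± 0.93 on slide 2 and 6.18 ± 1.01 with slide as a block (limma adjusted p = 0.148). Scaling of the dim arrays on slide 2 rested on undetected signal, which can raise genes detected there. Under the scanner-file labels, probes detected on all 6 arrays had a median log2 fold change of 0.73, against -0.47 over all genes. The rise of IL1B on slide 2 is therefore not separated from the scaling. PLAC8 was at least 34.5-fold lower on slide 1 and at least 18.6-fold lower on slide 2. Reference genes fell on slide 2 as well: before scaling, ACTB read 5655 on treated array 2 and 111 and 28.1 on the 2 dim arrays. A fall of this kind on slide 2 is therefore not particular to PLAC8, which also limits its fit with slide as a block. CSF1R had 5.50 ± 0.45 on slide 1 (adjusted p = 4.0e-04), -0.70 ± 1.11 on slide 2 (adjusted p = 0.640) and 2.40 ± 1.34 with slide as a block (adjusted p = 0.444). The median of ribosomal protein genes was 0.19 on slide 1, against -5.64 on slide 2. From the 4 brighter arrays under these labels, which add a control array to slide 1, it was -0.0052. No shift of this list the other way is therefore shown. Medians on slide 1 were -0.22 for oxidative phosphorylation, -0.41 for ribosome biogenesis, -0.03 for heat shock and -0.0066 for glycolysis. On slide 2, which holds the 2 dim arrays, they were -4.51, -3.45, -4.42 and -3.67. Cytokine genes had a median of 3.03 on slide 1 and of 0.98 on slide 2.

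**Figure D2:**
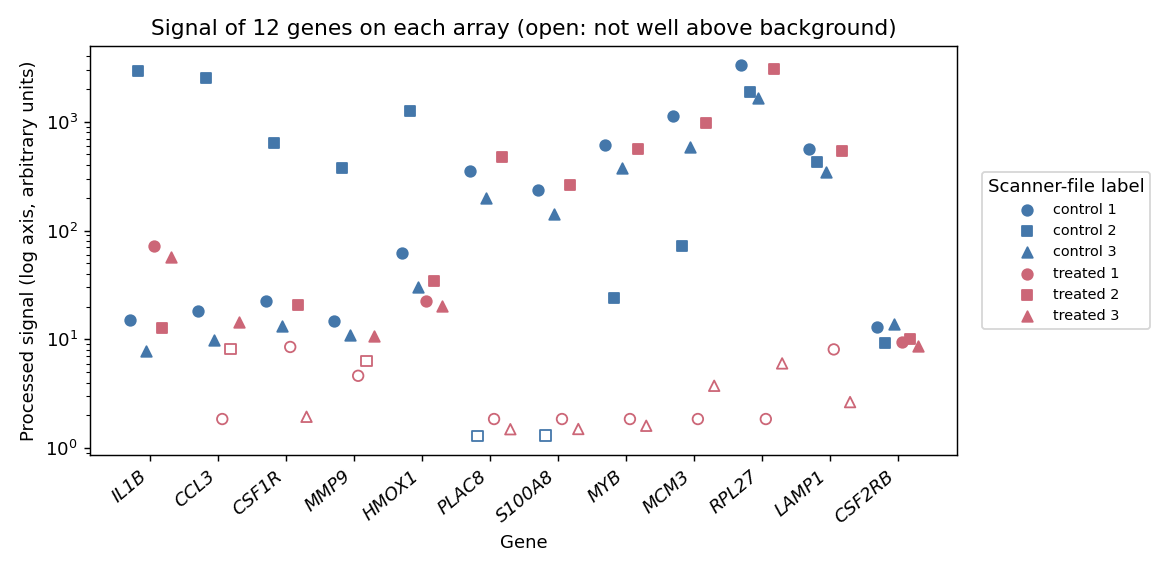
Processed signal (log axis) of 12 genes on each of the 6 arrays, named by scanner file, with open symbols where the spot was not well above background. IL1B read 2947 and PLAC8 1.3 on control array 2, against 15.0 and 349 on control array 1.

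The next comparison, chosen after the data were seen, leaves out the 2 dim arrays under the value-table labels. It sets 1 treated array, the scanner file of control array 2, against control array 1, control array 3 and the scanner file of treated array 2, and the lone array is assumed to vary like the controls. IL1B (hg19 chromosome 2, 113587429 to 113587488) was 328-fold higher in the treated sample, with a log2 fold change of 8.36 ± 0.51 (SE, 1 against 3 samples, limma adjusted p = 4.88e-06). CCL3, a chemokine that draws in leukocytes (chromosome 17, 34415605 to 34415664), had a fitted log2 fold change of 8.12 ± 0.55 (adjusted p = 9.82e-06). CCL3, MMP9, PLIN2, CD83, ITGA5 and PPARD were each not well above background on 1 of the 3 control arrays, so their fitted values are not exact folds. CSF1R was 44.1-fold higher at 5.46 ± 0.50 (adjusted p = 1.10e-04), and CSF2RB had -0.06 ± 0.55 (adjusted p = 0.998). PLAC8 (chromosome 4, 84012077 to 84015842) fell at least 40.8-fold, with a log2 fold change of -7.61 ± 0.54 (adjusted p = 1.05e-05). S100A8 (chromosome 1, 153362548 to 153362607) fell at least 25.9-fold at -6.95 ± 0.51. In all, 503 genes passed, 173 higher and 330 lower. That balance depends on the filter: 518 were higher and 372 lower with none, 245 and 134 with probes detected on at least 1 of the 4 arrays, and 138 and 105 with those detected on all 4. On slide 2, where the 2 dim treated arrays are set against their control, 39 of the 173 and 280 of the 330 had the same direction. Of those well above background on all 3 arrays of slide 2, 3 of 15 higher and 21 of 33 lower genes had the opposite direction there. Over all genes the median log2 fold change on slide 2 was -0.65, so lower was the common direction there. Keeping genes detected on the dim arrays favours the higher direction instead. Neither set of counts therefore bears on these genes alone.

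Of 5 measured inflammatory cytokine and chemokine genes, 4 rose (5 with p adjusted over the list alone), among them TNF at 2.75 ± 0.55 (adjusted p = 0.0111) and the neutrophil attractant CXCL1 at 2.70. The list's camera adjusted p was 1.06e-13 (adjusted p = 0.254 with an estimated correlation). Of 13 NF-kB regulators and targets, 4 rose and 1 fell (8 and 1 over the list alone). CD83, a marker of activated antigen-presenting cells, rose at 3.59 ± 0.56, BCL3 at 2.88 and TNFAIP8 at 2.63, while RELA, the p65 subunit itself, fell at least 10.6-fold. RELA was well above background on both dim arrays and had 0.81 on slide 2, and without the scanner file of treated array 2 its value moved from -3.78 to -4.42. The list had a camera adjusted p of 1.37e-07 (adjusted p = 0.254 with an estimated correlation). Of 11 genes of matrix proteases, adhesion and integrins, 4 rose (5 over the list alone), with the gelatinase MMP9 (chromosome 20, 44645121 to 44645180) at 5.57 ± 0.59, the hyaluronan receptor CD44 at 3.33 ± 0.50 and the integrins ITGB7 at 3.60 and ITGA5 at 3.28. That list had a camera adjusted p of 2.31e-06 (adjusted p = 0.337 with an estimated correlation). On slide 2 the NF-kB list had a median of -1.06 (camera adjusted p = 0.570). TNF had -2.24 there, CD83 -1.30 and CD44 -2.24, and none of these genes passed on slide 2. Most genes called higher were not well above background on all arrays of slide 2, so such values can rest on undetected spots.

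Of 23 lysosome and cathepsin genes, 5 rose (7 over the list alone), with the protease gene CTSL1 at 3.43 ± 0.54, the sphingolipid activator PSAP at 3.16, the cholesterol carrier NPC2 at 2.68 and CTSH at 2.18. The list's camera adjusted p was 2.84e-08 (adjusted p = 0.254 with an estimated correlation). Of 14 NRF2 oxidative stress genes, 4 rose (5 over the list alone), with the haem-degrading enzyme HMOX1 at 5.30 ± 0.52, SQSTM1 at 3.33, GCLC of glutathione synthesis at 2.66 and the ferritin gene FTH1 at 2.50. Their camera adjusted p was 5.28e-07 (adjusted p = 0.337 with an estimated correlation). Of 13 genes of lipid uptake, storage and efflux, 3 rose (3 up and 1 down over the list alone), with the lipid droplet protein PLIN2 at 5.34 ± 0.60, PPARD at 2.54 and APOC1 at 2.40, and MYLIP, not well above background in the treated sample, was at least 1.89-fold lower without passing (adjusted p = 0.0969). The lipid list had a camera adjusted p of 0.00236 (adjusted p = 0.262 with an estimated correlation). Of 18 genes of the unfolded protein and integrated stress response, the asparagine synthetase ASNS alone rose, at 2.37 ± 0.52 (2 rose over the list alone), and the list had a camera adjusted p of 3.52e-04 (adjusted p = 0.254 with an estimated correlation). Of 15 genes of MHC class I presentation 0 passed by limma, alone or over the list, with HLA-E at 1.44 (adjusted p = 0.192) and TAPBP at 0.74, and the list's camera adjusted p was 0.0298 (adjusted p = 0.659 with an estimated correlation). On slide 2 the medians lay the other way for the lysosome (-2.25), NRF2 (-2.37), lipid (-1.47), unfolded protein response (-1.38) and MHC class I lists (-4.86). Ribosomal protein genes had a median of -5.64 there and reference genes were dim too, so falls on slide 2 are not particular to these lists.

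Of 23 DNA replication genes, 14 fell (22 over the list alone), with the helicase subunits MCM3 at -3.24 ± 0.51 (adjusted p = 0.00291) and MCM4 at -3.49 (at least 2.40-fold), the sliding clamp PCNA, whose treated signal of 6.39 was not well above background, and GINS2 at -3.58 (at least 3.63-fold). The list's camera adjusted p was 1.19e-22 (adjusted p = 0.254 with an estimated correlation). Of 23 mitosis genes, 4 fell (13 over the list alone): the spindle motor KIF11 (at least 4.41-fold), TOP2A (at least 1.49-fold), BUB1, whose treated signal of 6.32 was not well above background, and BUB1B (log2 fold change -2.06). Mitosis had a camera adjusted p of 7.68e-11 (adjusted p = 0.254 with an estimated correlation). Of 13 myeloid progenitor and azurophil granule genes, 9 fell (11 over the list alone), with the transcription factors MYB at -4.04 ± 0.50 and GFI1 (at least 3.41-fold) and the granule proteases PRTN3 at -3.88 and CTSG (at least 16.5-fold). The progenitor list had a camera adjusted p of 3.60e-13 (adjusted p = 0.262 with an estimated correlation). Of 8 metallothionein and metal response genes, 2 fell (4 over the list alone), MT1X at -2.13 and MT1E at -2.06, with a camera adjusted p of 3.75e-04 (adjusted p = 0.541 with an estimated correlation).

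The remaining genes of the largest rises were the kinase SGK1 (log2 fold change 5.99), the amino acid oxidase IL4I1 (5.47), the stress cytokine GDF15 (5.34), RGS16 (5.17), the lysosomal thiol reductase IFI30 (5.11) and LPAR6 (4.76). Among the largest falls to a signal not well above background were GPR160 (at least 15.3-fold), P2RY2 (18.8-fold), CDCA7 (13.2-fold), the histone genes HIST1H3J (10.2-fold) and HIST1H1E (7.51-fold), the chemokine receptor CCR2 (7.57-fold), IRX3 (5.32-fold) and RASSF2 (4.79-fold). APBA1 (log2 fold change -4.67) and the RNA sensor gene DDX58 (-4.35) fell and stayed well above background. On slide 2, where both were well above background on all 3 arrays, APBA1 had 0.65 and DDX58 0.97, and without the scanner file of treated array 2 APBA1 moved to -5.50. With a normexp background model, 4 of the 503 genes passed (IL1B, CCL3, SGK1 and CSF1R), and without control array 3, 320 passed. The normexp model added an offset of 50 to each signal, which shrinks the fold changes of dim spots. Its count is thus not the effect of the background model alone. Under the scanner-file labels the same 4 brighter arrays set treated array 2 alone against the control arrays. Control array 2 then lies in the group that gives the spread, so a gene count from that fit decides nothing between the 2 sets of labels.

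**Figure D3:**
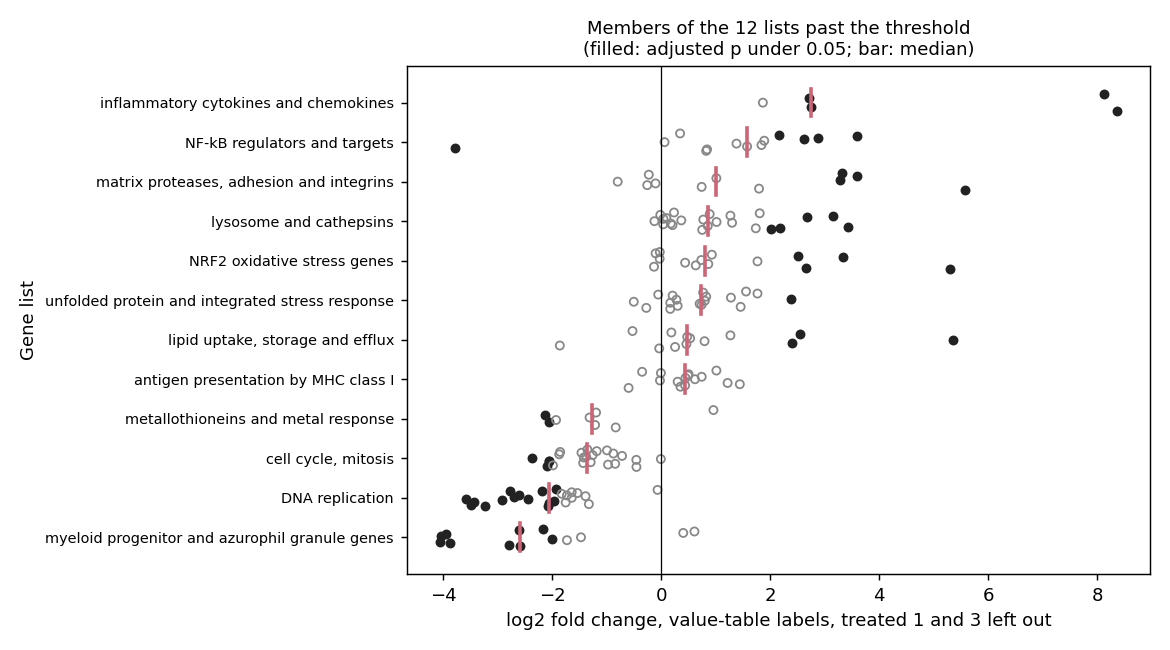
Log2 fold change of each measured member of 12 gene lists, from the 4 brighter arrays under the value-table labels, with filled points for an adjusted p under 0.05 and a bar at each list's median. DNA replication genes (median -2.06) lay below 0 and cytokine genes (median 2.75) above it.

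The share of spots well above background was 27.5% ± 3.42 in control and 17.0% ± 11.3 in treated arrays under the scanner-file labels (SD, n = 3, exact permutation test, two-sided p = 0.3). It was 28.8% ± 3.20 and 15.7% ± 8.98 under the value-table labels (exact p = 0.2). The 75th percentile of signal was 7.16 ± 1.98 in control and 4.52 ± 3.19 in treated arrays (SD, n = 3, exact p = 0.3), and 7.86 ± 1.77 and 3.82 ± 1.98 under the value-table labels (exact p = 0.2). Saturated spots numbered 0 on every array (exact p = 1). With 3 samples against 3, the smallest p that this test can give is 0.1.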

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

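The value-table labels with slide as a block or within slides, all alternatives without the 2 dim arrays, the displaced columns and the percentile over detected spots were chosen after the data were seen. For every change below the cause was not tested, unless fewer arrays or genes are named. Signal over background on treated arrays 1 and 3 limits each comparison that holds them. The normexp model added an offset of 50, which shrinks the fold changes of dim spots. The main gene count of 0 became 53 with no filter, 1 with slide as a block, 632 on slide 1, 2962 on slide 2, 503 under the value-table labels without the dim arrays, and 623 by an unadjusted test with a fold of at least 2. Leaving out each array gave 0 to 5846, the latter without treated array 2. The list count of 10 became 0 with an estimated correlation, 0 by fry, 2 with normexp, 5 with quantile normalization and 1 with median centring. It became 19 of 34 lists with no filter, 2 of 5 with probes detected on all 6 arrays and 4 of 25 without the displaced columns. It became 6 with a percentile over detected spots and 3 under the scanner-file labels without the dim arrays. Leaving out each array gave 2 to 11 lists, with 2 without treated array 3. The count of 503 genes (173 higher, 330 lower) became 4 with normexp (all higher), 890 with no filter (518 higher, 372 lower, 433 shared), 33 with probes detected on all 6 arrays (12 and 21) and 243 on all 4 (138 and 105). With probes detected on at least 1 of the 4 it was 379 (245 and 134, 212 shared). Leaving out each control gave 320 to 632, with 320 without control array 3. Its 12 of 29 lists became 20 of 34 with no filter, 1 of 5 with probes detected on all 6 arrays and 19 of 32 with probes detected on at least 1 of the 4. They became 0 with an estimated correlation, 7 by fry, and 12 to 13 without each control. Of the named genes in that comparison, 819 values kept their direction and side of the threshold, 91 no longer passed, 7 newly passed and 1 reversed. Without the dim arrays the scanner-file labels leave 1 treated array. Medians that turned there were MHC class I 0.28, mitosis 0.39, ribosome biogenesis 0.35, ribosomal proteins 0.60, glycolysis 0.38, oxidative phosphorylation 0.58 and heat shock 0.25. NRF2 genes had a median of -0.13 there, with the camera statistic upwards but not past the threshold. Under the value-table labels without them, medians were MHC class I 0.45, lysosome 0.85, unfolded protein response 0.72 and NRF2 0.80. For ribosomal proteins (-0.0052) and glycolysis (-0.028) there, and the lysosome list (-0.15) with slide as a block, the sign of the camera statistic was upwards and not past the threshold. CSF1R turned to 1.52 in the value table, 2.40 with slide as a block and 5.46 under the value-table labels without the dim arrays. CSF2RB turned to -0.10 with normexp, -0.56 with median centring, -0.46 under the scanner-file labels without the dim arrays and -0.063 under the value-table labels without them, where leaving out each control gave -0.24 to 0.22. Without the dim arrays the value-table labels also turned TAPBP to 0.74, GUSB to 0.042, LAMP1 to 0.21, PFKP to 0.074, PKM2 to 1.55, SLC3A2 to 0.77, SLC7A11 to 1.77, HSPA1B to 0.26 and PGD to 0.74. The scanner-file labels turned PSMB10 to 0.41, LAMP1 to 0.078, CENPF to 0.21, PRC1 to 0.37, GNL3 to 0.083, RPL27 to 0.24, RPS25 to 0.46, COX7B to 0.092, NDUFV1 to 0.14, HSPH1 to 0.033 and PGD to 0.16. Replicate as a block gave 0 genes by limma (1866 at an unadjusted p under 0.05) and 10 lists. Same-number pairs had correlations of -0.14, -0.00 and 0.23, against -0.23 to 0.21 for the other pairs. The treated deviations hold the 2 dim arrays and the labels of array 2 differ, so these values cannot decide whether the numbers pair. The median log2 fold change of all genes was -0.47, against -0.18 with normexp, -0.65 with quantile normalization and -1.55 with median centring. Slide as a block under the scanner-file labels could not be fitted, since each slide held 1 group.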

Other observations

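The tests on exchanged scanner files, on slide or scan and on labelled RNA below were chosen after the result was seen. The genes named in this and the next paragraph were chosen after their values were seen, and all values come from the 1 treated array of the value-table labels against 3 control arrays. Of 12 monocyte and macrophage surface markers, the co-stimulator CD86 (log2 fold change 2.45 ± 0.59, SE) and the integrin ITGAM (2.04 ± 0.54) rose, CCR2 fell, and the list had a camera adjusted p of 0.217. Of 7 calgranulins and antimicrobial genes, S100A8 and its partner S100A9 (at least 3.98-fold) fell and the oxidase subunit NCF1 (3.55 ± 0.53) rose (list p 0.590). Of 10 myeloid transcription factors, CEBPB (2.82 ± 0.50) rose and IRF8 (-4.12 ± 0.53) fell (list p 0.590). Of 5 osteoclast genes, NFATC1 (3.19) and TYROBP (2.19) rose and CA2 (-3.76) fell (list p 0.817). Of 6 genes of MHC class II presentation, IFI30 rose and HLA-DOA (at least 2.38-fold) fell (list p 0.213). Of 11 interferon-stimulated genes, DDX58 alone fell (list p 0.258), and it had 0.97 on slide 2.

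Of 8 JAK-STAT5 and SOCS feedback genes, the kinase PIM1 (3.03 ± 0.60) rose (list p 0.0673), and of 8 ERK pathway genes IER2 (2.78) rose (list p 0.371). Of 6 markers of alternative activation, IL1RN (2.70) rose (list p 0.425). The sterol genes INSIG1 (3.17) and SQLE (2.84) rose among 16 of cholesterol synthesis (list p 0.239). Of 11 p53 targets and cell death genes, TNFRSF10B (2.12) and BCL2A1 (1.97) rose and FDXR (at least 1.65-fold) and BCL2L11 (-3.64) fell (list p 0.590). PFKFB4 (2.29) rose among 20 of glycolysis and hypoxia (list p 0.708). CD86, NFATC1, PIM1 and PFKFB4 were each not well above background on 1 of the 3 control arrays, so their fitted values are not exact folds. Medians were -0.01 for 35 ribosomal proteins (list p 0.697), -0.34 for 26 of oxidative phosphorylation (list p 0.239), -0.47 for 18 of ribosome biogenesis (list p 0.0876) and -0.11 for 14 heat shock genes (list p 0.616), with 0 members past limma. Markers of erythroid cells and megakaryocytes had a median of -0.19 over 5 genes (list p 0.737). Markers of other cell types, T and NK (3 genes, 0.28), B (3, -0.06) and epithelial or fibroblast (2, -0.02), were too few to test, as were dendritic markers (4 genes, IRF8 fell) and colony-stimulating factor receptors and ligands (4 genes, CSF1R rose).

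Control array 2 stood apart among the brighter arrays: its correlations with the other 3 were 0.866 to 0.894, against 0.916 to 0.953 between those 3. Setting each of those 3 alone against the rest decides nothing, since control array 2 then lies in the group that gives the spread. Of the 503 genes called with control array 2 alone, 488 stayed past the threshold after a GC correction of each array, which argues against GC content. An exchange of the scanner files of control 2 and treated 2 would be a candidate explanation, and it predicts that the 2 dim arrays deviate from controls 1 and 3 the way control array 2 does. They lay lower than lists matched on level by a median of -0.93 over the genes called higher and -1.19 over those called lower, but most of these genes were not well above background on both dim arrays, so the medians decide nothing. Of the genes well above background on all 3 arrays of slide 2, 12 of 15 higher genes had the same direction there and 21 of 33 lower genes the opposite. Keeping genes detected on the dim arrays favours genes that read higher there. Under the scanner-file labels, probes detected on all 6 arrays had a median log2 fold change of 0.73, against -0.47 over all genes. These counts therefore decide nothing, and the question stays open. The effect of the treatment, under the value-table labels, stays open too and was not separated from a single array that differs for another reason.

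Treated arrays 1 and 3 were dim, with 8.55% and 12.7% of spots well above background. Slide or scan as the whole cause is argued against by treated array 2, which had 29.9% on the same slide. The displaced grid on treated array 1 is argued against by 9.64% outside the displaced columns, against 23.2% to 29.3% there on the brighter arrays. Less labelled sample RNA relative to the spike-ins may be the source. The 75th percentile on these 2 arrays was at most 0.171% of the brightest spike-in, against at least 0.357% on the other arrays. That spike-in read 1402 and 3080 on treated arrays 1 and 3, against 495 to 2647 on the others. The 75th percentile lay below the detection limit on both, so the ratio partly restates their dimness. Outside the displaced columns the 2 arrays had a correlation of 0.92 with each other and of 0.285 to 0.593 with the brighter arrays. A lower RNA amount through the treatment itself was not tested.

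The 6 arrays make 10 splits into 3 and 3, the real 1 included, too few for a share under 0.05. The real split gave 0 genes by limma (1377 at an unadjusted p under 0.05), and the highest of the others gave 0. For lists, the real split gave 10 and the highest other 10, and the 4 splits with 10 lists were those that keep the 2 dim arrays together, which points to a structure of the samples.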
